A study of Megalobrama amblycephala with 9 samples.

How the data were processed

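RNA sequencing was applied to blood of female blunt snout bream (Megalobrama amblycephala), a freshwater carp relative kept in aquaculture. Per the labels' protocols, blood was taken from the caudal vein with heparinised syringes, RNA was extracted with TRIzol and libraries followed standard Illumina protocols. The labels describe 9 samples. Of these, 8 belong to 4 stages with 2 samples each, namely immature fish at 1 year of age, immature fish at 2 years, mature fish at 2 years and fish of that age sampled 24 h after they had spawned. The remaining sample is a mixture of the 8 blood samples.

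The table used here pairs 90638 identifiers with an estimated read count and an FPKM value, and names a single sample, "blood", in every row. That word is the source name of all 9 samples, and 1 title, that of the mixture, also holds it. The values were therefore treated as one library, or one pool, of blood that cannot be assigned to a stage. Expression values per stage were not analysed here. The design fixed before the data were examined planned count-model tests between the stages, tests of preset gene lists and a replicate check. None of these was run, because the table holds a single column of each measure.

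The read counts were deposited as estimated counts per identifier, not scaled for depth, per the file headers and the values. They were recognised as estimates because 360 values are not whole numbers. The FPKM values (fragments per kilobase of length and per 1000000 fragments) were computed by the authors and deposited with 2 decimals. The submitters' processing notes name FastQC (read quality reports), fastp (read trimming) and Bowtie2 (short-read alignment), with no version or role. The reference that was aligned to, the counting program, the gene lengths behind the FPKM values and any filter are not given in the sources used here. The identifiers have a first number and a second number (c and g), a form that transcriptome assemblers write, and were used as they stand. None could be paired with a gene name: 0 of the 90638 identifiers matched any of the 38087 genes of the supplied RefSeq table (assembly ASM1881202v1). The preset gene lists and cell type markers therefore gave no values.

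Identifiers were ranked by estimated count, and shares were taken of the summed count of the table. CPM values (counts per 1000000 of that sum) were also computed. The 95% intervals of shares are exact Clopper-Pearson intervals on rounded counts. A count of 0 was read as at most 3 counts. Both cover counting error only, with reads taken as independent. Reads without molecular identifiers are not independent molecules, so both can be too narrow. An implied length was computed for each identifier as the estimated count divided by the FPKM value and by the summed count, scaled to nucleotides. It assumes that the summed count was the total behind the FPKM values. It is the length the FPKM value used, which can be shorter than the transcript where a program subtracts the fragment size.

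Non-whole counts were examined by adding them up within groups of at least 2 identifiers that share a first number, with sums within 0.02 of a whole number taken as whole, and by shuffling the non-whole counts between groups 10000 times with a one-sided permutation test. The sums of non-whole counts and the ratio used for low counts were each tested on simulated data for the 90638 identifiers. In 200 simulated groups with divided reads 100% of sums were whole, against 2.5% with random fractions. Among simulated counts, the number of identifiers with 4 reads relative to the geometric mean of the numbers with 3 and 5 was 0.99 when single reads were drawn and 3.24 when both mates were counted. The depth was 17229132 estimated counts in total, so a count of 0 allows up to 0.174 CPM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were another floor for counting an identifier as measured, FPKM in place of counts, rounding, leaving out the 20 most abundant identifiers and thinning of the reads.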

Results

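The study was laid out to follow gene expression in blood of female blunt snout bream from the immature stage at 1 and 2 years of age, through maturity at 2 years, to 24 h after spawning, with 2 samples per stage in 4 stages. The table analysed here holds values for blood under a single sample name, with no stage attached. Each value below describes that blood library or pool as the authors gave it. There were no replicates, so no value has a spread between samples. No comparison between ages, between immature and mature females, or between mature and spawned females was made, and the identifiers carry no gene names, so no gene, pathway or blood cell type is named.

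In this blood column, 2 identifiers stood well above the others. The 2 most abundant identifiers held 18.8% of the 17229132 estimated counts (95% exact interval 18.79 to 18.82%). The first, c52731_g1, held 1730887 estimated counts, or 10.05% of the total (95% exact interval 10.03 to 10.06%), with 276098 FPKM. The second, c84433_g1, held 1509108 estimated counts, or 8.76% (95% exact interval 8.75 to 8.77%), with 245442 FPKM. Their counts differed by a ratio of 1.15. Their exact intervals did not overlap, but these cover counting error only, with no spread between samples. The length implied by count and FPKM was 364 nt for the first and 357 nt for the second. The third identifier held 2.39% of the counts, and the second exceeded it 3.66-fold. In CPM, the first stood at 100463, the second at 87590 and the third at 23904.

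Below these, the counts spread over a long list. The 10 most abundant identifiers held 24.97% of all counts, the top 100 held 39.6%, the top 1000 held 67.2% and the top 10000 held 95.2%. It took 253 identifiers to reach 50% of the counts. On the FPKM scale, which divides by length, the 2 most abundant identifiers took 31.3% of the summed FPKM and 89 identifiers reached 50%.

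**Figure D1:**
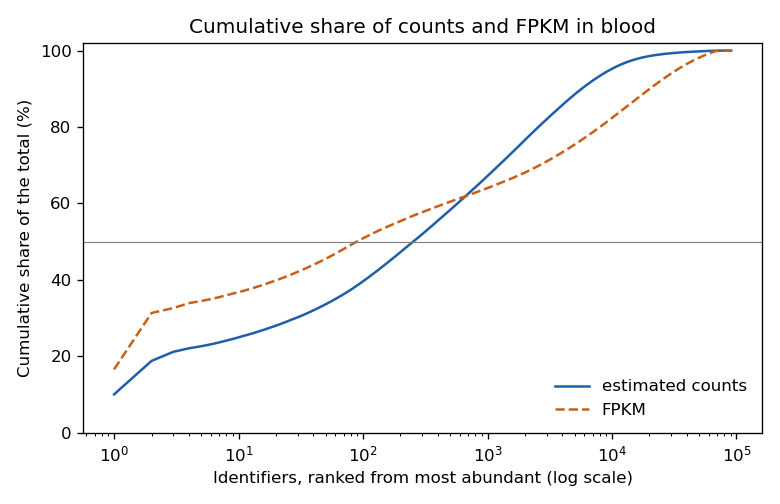
Cumulative share of the total (y axis, percent) against identifiers ranked from the most abundant (x axis, log scale), for estimated counts (solid line) and FPKM (dashed line) in the one blood column; the grey line marks 50%. The count line crosses 50% at 253 identifiers and the FPKM line at 89.

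Reads were assigned to 71282 of the 90638 identifiers (78.6%), and 19356 (21.4%) were listed at 0, which allows up to 0.174 CPM for each. Among identifiers with reads the median was 5 estimated counts and 3.98 FPKM, so most were measured with little precision. Fewer than 3 estimated counts, but above 0, were found for 23229 identifiers, which together held 0.213% of the counts. A further 20652 had 3 to under 10 counts and held 0.584%. Between 10 and under 100 counts were found for 16100 identifiers (3.10% of counts), between 100 and under 1000 for 8950 (17.2%), and between 1000 and under 10000 for 2149 (31.5%). The 202 identifiers with 10000 or more counts held 47.4% of the counts.

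**Figure D2:**
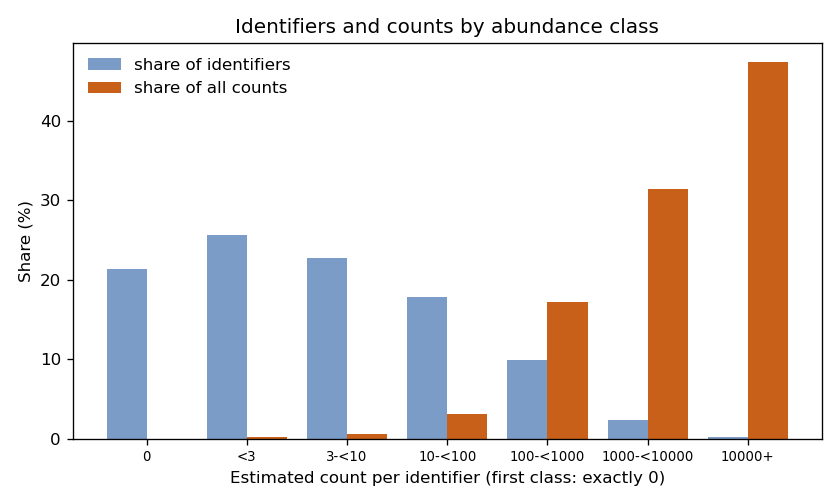
Share of all identifiers (blue bars) and share of all estimated counts (orange bars), in percent on the y axis, for classes of the estimated count per identifier on the x axis, in the one blood column. The class of 10000 or more counts holds 0.223% of the identifiers and 47.4% of the counts, while 21.4% of the identifiers are at 0.

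Counts and FPKM ranked the identifiers differently. Of the top 1000 by count, 601 were also in the top 1000 by FPKM. The implied length had a median of 131 nt over the 71282 identifiers with reads, with a 5th percentile of 5.12 nt and a 95th percentile of 2034 nt. Values near 5.12 nt cannot be whole transcript lengths, so implied lengths are not read here as transcript sizes. Among the 11301 identifiers with at least 100 counts the median was 1430 nt, and 7698 of them exceeded 1000 nt. Implied lengths under 200 nt were found for 41657 identifiers (58.4% of those with reads), which held 1.88% of the counts and 27.2% of the summed FPKM. The 17146 identifiers over 500 nt held 71.2% of the counts, with a median of 145 counts, against a median of 3 counts in the remainder with reads. Of the 20 highest FPKM values, 7 belonged to identifiers with an implied length under 100 nt, and 5 of these 7 were also among the top 1000 by count. The highest-ranked of the other 2, at rank 9 by FPKM with 7705 FPKM, rested on 579 estimated counts, rank 3764 by count, and an implied length of 4.36 nt.

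Identifiers that share a first number made up 20.1% of the table, or 18262 identifiers. Estimated counts that are not whole, were found for 360 identifiers. These held 2.69% of all counts, and 358 of them shared their first number with another identifier.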

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

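All alternatives here were chosen after seeing the data, since those planned concerned comparisons between stages that were not run. No paired analysis was possible because the values carry a single sample name and no replicate number; leaving out a replicate was likewise not possible. The number of identifiers with reads, 71282, was 71280 with at least 1 estimated count, 48053 with at least 3 and 67671 with at least 1 FPKM, and fell to 27401 with at least 10. Thinning the reads to 50% left 61859 identifiers, to 25% left 50415 and to 10% left 36962, so the number had not levelled off at this depth. The share of the 2 most abundant identifiers, 18.8%, was 31.3% of the summed FPKM, 18.96% among identifiers with at least 10 counts and 18.8% with rounded counts. The 253 identifiers that hold 50% of the counts became 89 with FPKM, 765 without the 20 most abundant and 244 among identifiers with at least 10 counts. The FPKM setting differs from the counts by its division by length, and the settings with at least 10 counts or without the 20 most abundant differ by the identifiers they leave out. Depth limited many single identifiers: 43881 of those with reads had under 10 counts.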

Other observations

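All tests in this part were chosen after the values had been seen, and no biological explanation was tested, because the one blood column has no stage to compare.

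The non-whole counts may come from reads divided between identifiers that share a first number. In 170 of 171 groups with at least 2 such identifiers, or 99.4%, the counts added up to a whole number, against a mean of 5.11% and a highest value of 12.3% after shuffling the counts between groups (one-sided permutation test, p = 0.0001, the smallest that 10000 shuffles can give). What these identifiers have in common was not tested.

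Zero values were tested against the same idea, that a partner with the same first number took the reads. Of the 19356 identifiers at 0, 16899 or 87.3% have no partner with the same first number. For these, a partner cannot have taken the reads. Only 18262 identifiers (20.1% of the table) share a first number, fewer than are at 0. Partners could therefore not have been the whole cause, whatever the counts. The share at 0 was 23.3% among identifiers without a partner and 13.5% among those with one. Reads taken by identifiers with another first number, and identifiers that come from reads outside this column, stay open and were not tested.

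Low counts had an unusual shape: 9731 identifiers had a rounded count of 1, 13495 had 2 and 6728 had 3, so the number at 2 was 1.67 times the geometric mean of its neighbours (95% interval 1.63 to 1.71). From 2 to 8 the numbers fell at each step, to 4199 at 4, 2261 at 6 and 1440 at 8. The number at 1 lay below that at 2, so the ratio cannot tell too few identifiers at 1 from too many at 2. Counting both mates of each read pair would raise the other even counts too, but the ratio was 0.93 at 4 (95% interval 0.90 to 0.97) and 0.97 at 6 (95% interval 0.92 to 1.02), which argues against it. A single cut-off on the FPKM values before deposit cannot have removed identifiers with reads and up to 200 nt of implied length. At 200 nt, 1 read gives 0.290 FPKM, and the lowest value above 0 was 0.12. Identifiers of up to 200 nt make up 29489 of the 29954 identifiers with 1 to 3 reads (98.4%). Their ratio at 2 was 1.69 (95% interval 1.66 to 1.73), which is no separate test, because nearly the same identifiers gave the 1.67. The raised ratio is thus present where an FPKM cut-off takes nothing away, which argues against such a cut-off as its cause among these identifiers. Why few identifiers had 1 read was not tested. Filters on other measures were not tested. A removal of low values among long identifiers stays open and cannot be decided here. Among the 17146 identifiers over 500 nt, 0 held 1 to 3 reads. For 1 read this follows from the lowest listed FPKM value, which comes from these same values. It also follows for 2 or 3 reads in the longer of them, but not in the shorter.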
